A study of Homo sapiens with 6 samples.

How the data were processed

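The 6 libraries were made from HCC827 cells, 3 from 3D culture in Matrigel and 3 from 2D culture in flasks. Per the labels' protocols, total RNA was treated with DNase, samples with an RNA integrity number above 9 were used, poly(A) RNA was isolated, a directional library kit was used, and single-end reads of 75 nt were sequenced on a NextSeq instrument. The authors deposited 1 table of TPM per gene and library for 60504 genes of all biotypes, rounded to 2 decimals; each column sums to 1000000 apart from rounding. Per the submitters' processing notes, cutadapt 2.3, STAR 2.7.0d and RSEM 1.3.1 were used with the build hg38; the notes give no role or order for these tools. The annotation release, the strand setting of the counting and any filter are not given in the sources used here, so antisense and overlapping genes are treated as uncertain. TPM keeps no depth, so the depth of each library is unknown, no counting interval is given, and an exact 0 means only that a gene is listed at 0. TPM is also a share of each library's RNA: a rise of some genes lowers the values of the rest.

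Groups and replicate numbers were taken from the sample titles, and every library column of the table was matched to 1 sample. Genes with a mean of at least 1 TPM over the 6 libraries, 15042 in number, were tested on log2(TPM + 1) with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, as 3D against 2D with no covariate. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A fold change on this scale understates the change of genes with low TPM. An exact test of 3 libraries against 3 cannot give a p under 0.1, so single genes were tested only in the model across all genes.

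A total of 46 gene lists covering metabolism, cell cycle, stress, immune, signalling, matrix and lung cell type genes, with markers of other cell types, were fixed with the tests, the rule for named genes and the alternative settings before the data were examined. The 42 lists with at least 5 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Alternatives for the lists were camera with an estimated correlation, limma's fry and the median of the members. Each list's count of called genes was given over all genes and with adjustment over the list alone. The rule named 3 kinds of genes. The first were the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 10 TPM in the higher group, all libraries of the groups apart, and a gene name other than a clone or LINC name. The second were up to 3 called members per list in the main direction and up to 1 in the other, or the 2 most abundant members where none was called. The third were fixed genes of this cancer such as EGFR, MET and CD274. Some genes and 1 list picked by these rules are not reported here. SFTPC, CA9, KRT16, KRT16P2, HLA-DRA, COL1A2, COL3A1, CDH2, ZEB1, GAPDH, PGK1 and the levels of leukocyte genes were given outside the rule, chosen after their values were seen.

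The alternative settings fixed in advance were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 TPM, median-ratio scaling, quantile normalization, leaving out genes of the mitochondrial genome or the 50 most abundant genes, eBayes without a trend or with its robust option, the replicate number as a block, and each library left out in turn. Added after seeing the data were leaving out both libraries numbered 3, a correction for transcript length and GC content, and protein-coding nuclear genes only. Coordinates, transcript lengths and GC content came from GENCODE 29 on GRCh38, in which 14874 of the tested identifiers (98.9%) were found; the release the authors used may be another.

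The fit was tested on simulated data for this comparison, with 3 simulated libraries per group and 200 changed genes. Of 14977 genes in that step, it called 2.99% of genes changed 1.5-fold, 34.3% of those changed 2-fold and 75.8% of those changed 4-fold, and 3 of 14784 unchanged genes. In the same way 4 of 4 shifted lists and 0 of 34 unshifted lists were called over 15042 genes. The simulated genes varied independently, whereas members of the real lists can vary together, with an estimated correlation of 0.961 for the mitosis list. The simulation therefore does not show how often camera at its preset correlation calls unchanged lists in these data. The real comparison called 1855 genes, so its adjusted threshold was reached at a larger unadjusted p than with 200 changed genes. The simulated shares of changed genes called therefore do not give the sensitivity of the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.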

Results

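RNA was measured in HCC827, a human lung adenocarcinoma cell line with mutant EGFR, grown in 2 ways. In the 2D group the cells grew as a monolayer in flasks for 4 to 6 days. In the 3D group they grew as tumoroids inside droplets of growth factor reduced Matrigel, a basement membrane gel, for 12 to 16 days. Each group held 3 libraries of poly(A) RNA, and the comparison addressed how gene expression in this line differs between the 2 cultures. The values were TPM, shares of transcripts scaled so that every library sums to the same total, which keep no record of sequencing depth, so the depth of each library is unknown here and no counting interval is given. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Culture time, the number of cells seeded (fewer in 3D) and contact with the gel differed between the groups together with the geometry. Their effects cannot be told apart here.

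The first principal component of log2(TPM + 1) held 52.7% of the variance and separated the 2 cultures. The second held 19.5% and set the third library of each group apart from the other libraries of its group, most of all 2D replicate 3. Pearson correlations across genes, which are not independent replicates, lay between 0.957 and 0.980 within groups and between 0.919 and 0.948 across groups. Genes listed above 0 numbered 24926 to 26387 in the 3D libraries and 23908 to 24583 in the 2D libraries. Transcripts of the mitochondrial genome took 12.3% to 19.4% of the TPM in 3D and 14.4% to 17.5% in 2D.

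**Figure D1:**
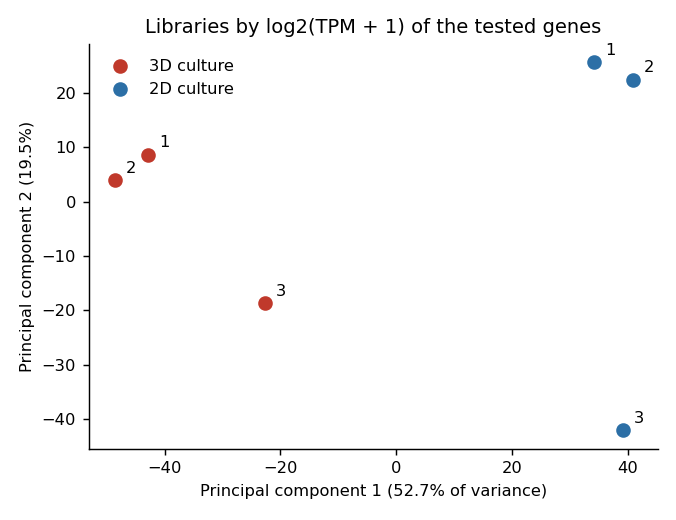
Principal components 1 and 2 of log2(TPM + 1) over the tested genes, 1 point per library, coloured by culture and numbered by replicate. The 3D libraries sit at negative and the 2D libraries at positive values of component 1, and 2D replicate 3 has the lowest component 2 score at -42.0.

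More genes were called higher than lower in 3D on the TPM scale. Of 15042 genes with a mean of at least 1 TPM, 1536 were higher and 319 were lower in 3D (limma, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold on the log2(TPM + 1) scale was reached by 717 of the higher and 111 of the lower genes, and 4727 genes had an unadjusted p under 0.05. In all 1855 called genes the 3 libraries of a group lay wholly above or below the others, which the test itself selects for. Such separation was seen in 36.7% of tested genes, where chance gives 10%. The called genes included 1623 protein-coding genes and 232 of other biotypes.

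The balance between directions differed between scales. The median log2 fold change of all tested genes was 0.12 rather than 0. It depended on abundance, being -0.03 in the fifth of genes with the highest mean TPM and 0.10 to 0.20 in the others. With libraries rescaled by median ratios the split was 931 higher and 662 lower (58.4% higher, against 82.8%), with quantile normalization 869 and 576 (60.1% higher), and the median gene then lay at -0.03 and -0.04. No gene called in the main comparison was called in the other direction in either. Both methods centre the typical gene and so move the split towards balance by design, which does not decide the cause of the excess. Single libraries also moved the counts. Higher and lower genes numbered 367 and 29 without 3D replicate 1, 390 and 41 without 3D replicate 2, 731 and 74 without 2D replicate 1, and 425 and 53 without 2D replicate 2. They numbered 1607 and 551 without 3D replicate 3 and 1587 and 563 without 2D replicate 3. Without the filter on low TPM, 729 and 86 were called, and 56 of the 131 called genes named by rule lost their call, among them each gene given below as losing its call, apart from NDRG1, SREBF1 and PHGDH. In an analysis chosen after seeing the data, leaving out both libraries numbered 3 gave 2464 and 1356.

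**Figure D2:**
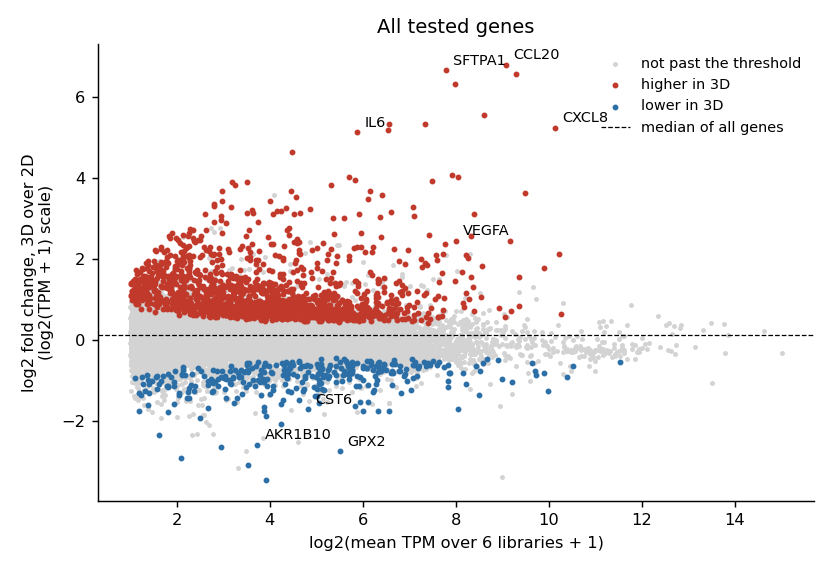
Log2 fold change of 3D over 2D against the log2 mean TPM for all 15042 tested genes, with genes past the adjusted threshold in colour and the median of all genes as a dashed line. The 1536 genes in red were higher and the 319 in blue lower in 3D, and the median gene lay at 0.12, while under median-ratio scaling it lay at -0.03.

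Chemokines and cytokines that NF-kB controls were among the largest increases in 3D. CCL20, a chemokine that attracts lymphocytes and dendritic cells, rose from 9.51 ± 5.34 TPM in 2D to 1078 ± 222 TPM in 3D (mean ± SD, n = 3 each; limma log2 fold change 6.79, SE 0.36, adjusted p = 0.00015). The neutrophil chemokine CXCL2 rose from 12.3 ± 3.63 to 1237 ± 277 TPM (log2 fold change 6.56, SE 0.25) and CXCL8, another neutrophil chemokine, from 62.7 ± 37.0 to 2183 ± 434 TPM (5.24, SE 0.38). The inflammatory cytokine IL6 rose from 2.32 ± 0.878 to 114 ± 15.1 TPM, and TNFAIP3, a feedback inhibitor of NF-kB signalling, from 3.40 ± 1.12 to 183 ± 76.3 TPM. TREM1, a receptor that amplifies inflammatory signalling in myeloid cells, rose from 3.96 ± 0.809 to 180 ± 37.3 TPM. Of the 31 measured NF-kB targets, chemokines and cytokines, 15 rose, 1 fell and 15 did not pass the test, and 22 rose and 1 fell when adjusted over the list alone. The member that fell was the cytokine IL18, with 13.9 ± 1.83 TPM in 3D against 25.3 ± 5.25 in 2D, a call that was lost without 3D replicate 1, 3D replicate 2 or 2D replicate 2 (limma, adjusted p up to 0.118 over the alternatives). The list stood above other genes (limma's camera, adjusted p = 5.73e-11, median log2 fold change 1.45), with adjusted p = 0.60 with an estimated correlation.

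Immediate early genes, which cells transcribe within minutes of a stimulus, moved together. Of 24 measured members, 21 rose, none fell and 3 did not pass the test, and 24 rose when adjusted over the list alone. ATF3, a stress-induced transcription factor, rose from 14.9 ± 2.47 to 763 ± 258 TPM (limma log2 fold change 5.54, SE 0.25, adjusted p = 0.000119). FOSB, a subunit of the AP-1 transcription factor, rose from 6.58 ± 1.13 to 315 ± 125 TPM, the nuclear receptor NR4A1 from 2.08 ± 0.457 to 39.9 ± 13.9 TPM, and EGR1 from 70.7 ± 12.1 to 364 ± 8.48 TPM. The median of the list was 2.04 (camera, adjusted p = 2.05e-17), with adjusted p = 0.60 with an estimated correlation. MYC, a growth-promoting transcription factor, rose from 100.4 ± 9.00 to 317 ± 30.2 TPM (log2 fold change 1.65, SE 0.13). Every gene named as rising in these 2 paragraphs kept its call under each alternative run.

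**Figure D3:**
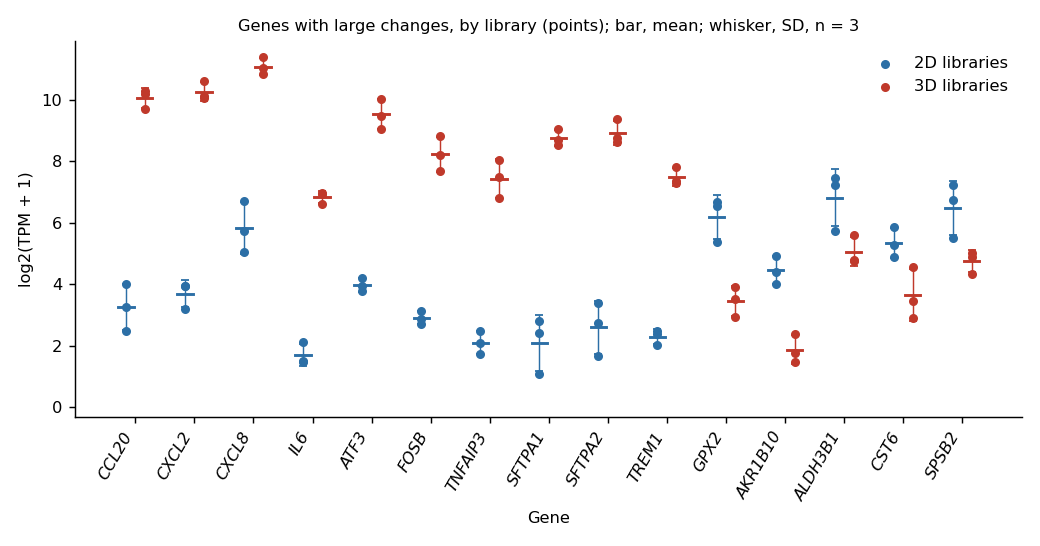
TPM of 15 of the 20 genes with the largest changes in either direction, as log2(TPM + 1), with 1 point per library, the mean as a bar and the SD over 3 libraries as a whisker. The 10 genes on the left were higher in every 3D library than in any 2D library, CCL20 at a mean of 1078 against 9.51 TPM, and the 5 on the right were lower.

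Surfactant protein genes of the alveolar type II cell, the lung cell that secretes surfactant, rose with them. SFTPA1 rose from 3.82 ± 2.50 to 435 ± 81.9 TPM (limma log2 fold change 6.65, SE 0.41, adjusted p = 0.000267) and SFTPA2 from 5.79 ± 3.63 to 496 ± 142 TPM (6.32, SE 0.41). These paralogs are nearly identical, and how reads were divided between them is uncertain. SLC34A2, a phosphate transporter of type II cells, rose from 1.85 ± 0.766 to 23.1 ± 14.8 TPM. Of 16 measured type II cell genes, 5 rose, 1 fell and 10 did not pass the test, and 7 rose and 1 fell when adjusted over the list alone. LPCAT1, which makes surfactant phospholipid, fell from 1433 ± 503 to 586 ± 170 TPM, a call lost with no trend in the fit and without 3D replicate 1 or 2 or 2D replicate 1 or 2 (limma, adjusted p up to 0.148 over the alternatives). SFTPC, the classical marker of mature type II cells, stood at 0.26 TPM on average in 3D and 0.0233 in 2D, below the filter. NKX2-1, the lung lineage transcription factor that drives surfactant genes, had 66.5 ± 11.7 TPM in 3D and 62.2 ± 3.52 in 2D (log2 fold change 0.08, SE 0.15). The list had a median of 0.59 (camera, adjusted p = 0.0452), with adjusted p = 0.72 with an estimated correlation, and lost the preset call at a mean of at least 5 TPM, with no trend, and without 3D replicate 3, 2D replicate 3 or both.

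Many genes induced by low oxygen were higher in 3D. Of 23 measured members of the hypoxia response, 13 rose, none fell and 10 did not pass the test, with 18 rising when adjusted over the list alone. VEGFA, the main growth factor of blood vessels, rose from 77.4 ± 19.3 to 433 ± 136 TPM (limma log2 fold change 2.46, SE 0.26, adjusted p = 0.00237). ANKRD37, a direct target of the hypoxia-inducible factor, rose from 4.52 ± 0.541 to 36.3 ± 4.21 TPM. NDRG1, a stress gene induced by hypoxia, rose from 101.8 ± 69.2 to 538 ± 109 TPM and lost its call without 3D replicate 2 (limma, adjusted p = 0.0576). Within 2D it was highest in replicate 3, at 181 against 68.5 and 55.6 TPM. CA9, a carbonic anhydrase often used as a hypoxia marker, stayed below the filter at a mean of 0.417 TPM in 3D and 0.0133 in 2D. The list median was 1.36 (camera, adjusted p = 1.56e-05), with adjusted p = 0.72 with an estimated correlation. Among 20 measured angiogenic factors 7 rose, none fell and 13 did not pass the test, with 8 rising when adjusted over the list alone. SEMA3F, a semaphorin that restrains vessel growth, rose from 0.163 ± 0.103 to 3.55 ± 1.12 TPM. The list had a median of 0.57 (camera, adjusted p = 0.0452), with adjusted p = 0.60 with an estimated correlation, and its preset call was lost at a mean of at least 5 TPM and without 3D replicate 3, 2D replicate 2 or both libraries numbered 3.

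Some interferon-induced genes and genes of antigen presentation by MHC class I were also higher. Of 41 measured interferon response genes, 10 rose, none fell and 31 did not pass the test, and 17 rose when adjusted over the list alone. GBP1, a guanylate-binding protein induced by interferon gamma, rose from 18.3 ± 4.76 to 96.4 ± 33.0 TPM (limma log2 fold change 2.31, SE 0.28, adjusted p = 0.00423). IRF1, a transcription factor of the interferon response, rose from 26.0 ± 7.19 to 119 ± 22.7 TPM. The list median was 0.97 (camera, adjusted p = 2.25e-06), with adjusted p = 0.72 with an estimated correlation. Of 19 MHC class I genes, 6 rose, none fell and 13 did not pass the test, with 7 rising when adjusted over the list alone. HLA-B, a class I heavy chain, rose from 188 ± 35.4 to 471 ± 96.0 TPM (log2 fold change 1.32, SE 0.20); class I genes resemble one another, so the division of reads among them is uncertain. The class I list had a median of 0.35 (camera, adjusted p = 0.0482), with adjusted p = 0.74 with an estimated correlation, and lost the preset call with a pseudocount of 5, with no trend, and without 3D replicate 3, 2D replicate 2 or both libraries numbered 3.

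Of 9 immune checkpoint ligands and related genes, 3 rose, none fell and 6 did not pass the test, and the same numbers held when adjusted over the list alone. IDO1, a tryptophan-degrading enzyme that dampens T cell responses, rose from 1.29 ± 0.0700 to 19.6 ± 5.62 TPM (limma log2 fold change 3.13, SE 0.21, adjusted p = 0.000379). HHLA2, a B7 family ligand, rose from 71.9 ± 11.5 to 155 ± 20.3 TPM. CD274, which encodes PD-L1, rose from 12.9 ± 2.26 to 25.9 ± 4.55 TPM (0.95, SE 0.19), and lost its call without 3D replicate 2, 2D replicate 1 or 2D replicate 2 (limma, adjusted p up to 0.08 over the alternatives). The list had a median of 0.44 (camera, adjusted p = 0.0482), with adjusted p = 0.60 with an estimated correlation, and lost the preset call with a pseudocount of 5, at a mean of at least 5 TPM, with no trend, and without 3D replicate 3, 2D replicate 3 or both. Of 24 genes of the unfolded protein response, 3 rose, none fell and 21 did not pass the test, with 4 rising when adjusted over the list alone. XBP1, a transcription factor of that response, rose from 68.4 ± 18.7 to 127 ± 12.7 TPM (0.92, SE 0.21), a call lost under median-ratio scaling and without 3D replicate 1, 3D replicate 2 or 2D replicate 2 (limma, adjusted p up to 0.121 over the alternatives). The median of this list was 0.31 (camera, adjusted p = 0.0112), with adjusted p = 0.72 with an estimated correlation.

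The genes that fell in 3D included enzymes that NRF2, the regulator of the antioxidant response, switches on. AKR1B10, an aldo-keto reductase, fell from 21.7 ± 7.21 TPM in 2D to 2.81 ± 1.27 in 3D (limma log2 fold change -2.58, SE 0.30, adjusted p = 0.0037). ABCC2, an exporter of conjugated compounds, fell from 45.7 ± 3.62 to 17.2 ± 2.84 TPM (-1.37, SE 0.16). Of 27 measured NRF2 targets, 5 fell, none rose and 22 did not pass the test, and 11 fell and 1 rose when adjusted over the list alone. The list median was -0.46 (camera, adjusted p = 6.5e-06), with adjusted p = 0.60 with an estimated correlation. Other large decreases, outside that list, were in GPX2, a glutathione peroxidase, from 78.0 ± 32.8 to 10.4 ± 3.79 TPM (-2.74, SE 0.38), in ANXA2R, an annexin receptor, from 22.6 ± 4.56 to 5.50 ± 1.61 TPM, and in the small nucleolar RNA gene SNORD3B-1, from 19.6 ± 5.01 to 1.49 ± 0.808 TPM, a copy of a repeated gene whose short RNA a poly(A) library samples poorly. The cysteine protease inhibitor CST6, the aldehyde dehydrogenase ALDH3B1 and the ubiquitin ligase adaptor SPSB2 also fell, with log2 fold changes of -1.70, -1.75 and -1.74. Each of these 3 lost the call without 3D replicate 1 or 2 or 2D replicate 1 or 2, and CST6 also without 2D replicate 3. CST6 and ALDH3B1 also lost it with no trend, with the robust option and after a correction for gene length and GC content, and ALDH3B1 with the replicate block (limma, adjusted p up to 0.145, 0.154 and 0.132 over the alternatives).

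Genes of respiration, translation and cell division had mostly negative log2 fold changes, with few single calls. Of 45 nuclear-encoded genes of oxidative phosphorylation all had a negative log2 fold change, 7 fell and 38 did not pass the test, and 15 fell when adjusted over the list alone. COX6B1, a subunit of cytochrome c oxidase, had 269 ± 39.1 TPM in 3D and 416 ± 40.5 in 2D (log2 fold change -0.63, SE 0.15), and its call was lost with no trend, with the replicate block, after the length and GC correction and without 3D replicate 1 or 2 or 2D replicate 1 or 2 (limma, adjusted p up to 0.145 over the alternatives). The list median was -0.38 (camera, adjusted p = 1.05e-14), with adjusted p = 0.60 with an estimated correlation. The 13 measured genes of the mitochondrial genome had positive values with a median of 0.36, and none passed the test; as a list they were called only under quantile normalization, without 3D replicate 3 and without both libraries numbered 3. Of 75 cytosolic ribosomal proteins 2 fell, none rose and 73 did not pass the test, and none passed when adjusted over the list alone. Their median was -0.25 (camera, adjusted p = 1.65e-12), with adjusted p = 0.72 with an estimated correlation. RPLP0 had 2436 ± 242 TPM in 3D and 3526 ± 81.4 in 2D, and its call was lost under quantile normalization, with no trend, with the replicate block, after the length and GC correction and without 3D replicate 1 or 2 or any single 2D library (limma, adjusted p up to 0.264 over the alternatives). Of 35 genes of DNA replication 3 fell, 1 rose and 31 did not pass the test, with the same numbers when adjusted over the list alone. E2F1, a transcription factor of the G1/S transition, fell from 21.7 ± 4.15 to 8.35 ± 3.59 TPM, a call lost without 3D replicate 1 or 2 or 2D replicate 1 or 2 (limma, adjusted p up to 0.0993 over the alternatives). The replication list had a median of -0.58 (camera, adjusted p = 5.73e-11), with adjusted p = 0.72 with an estimated correlation. None of 32 mitosis genes passed the test, over all genes or adjusted over the list alone, although all had negative values with a median of -0.57 (camera, adjusted p = 2.16e-05). That call was lost without 2D replicate 3 and gave adjusted p = 0.74 with an estimated correlation. The proliferation marker MKI67 had 6.33, 8.53 and 19.1 TPM in the 3D libraries and 10.3, 12.2 and 44.3 TPM in the 2D libraries, with the highest value of each group in replicate 3. It was called lower only with the replicate number as a block (limma, adjusted p = 0.045).

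In all, 9 lists were called higher and 5 lower of 42 tested. None was called with an estimated correlation in camera, where the smallest adjusted p was 0.60 and 2 lists had an unadjusted p under 0.05, while limma's fry, which asks only whether a list moves on balance, called 17 higher and 2 lower. Of the 14 lists fry did not call the interferon, MHC class I, mitosis, DNA replication and ribosomal protein lists (adjusted p = 0.0946, 0.0866, 0.51, 0.158 and 0.0866). Over the alternatives the highest adjusted p of each of the 14 lists was the one with an estimated correlation, and the lowest ran from 1.13e-23 for immediate early genes to 0.00775 for checkpoint ligands. Dividing the 6 libraries in the 9 other ways into 3 and 3 gave 5 to 17 called lists. Each of these divisions set 2 libraries from 1 culture with 1 from the other, so it kept part of the culture difference. Calls in them can carry that difference. The number of called lists therefore does not separate the cultures from other groupings of these libraries, and it cannot show that the lists are unrelated to culture. For 5 of the 14 lists the preset p of the culture comparison was below that of each other division, namely immediate early genes, NF-kB targets, oxidative phosphorylation, NRF2 targets and angiogenic factors. Of these only angiogenic factors were called in none of the 9 other divisions, while immediate early genes were called in 8, oxidative phosphorylation in 7, NRF2 targets in 5 and NF-kB targets in 4. The angiogenic list shares VEGFA, its largest rise, with the hypoxia list, which was called in 4 of the other divisions. Among the 9 lists left, other divisions gave a p as small in 6 cases for mitosis, 4 for MHC class I, 3 each for the interferon and type II lists, 2 each for hypoxia and DNA replication, and 1 each for checkpoint ligands, the unfolded protein response and ribosomal proteins.

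**Figure D4:**
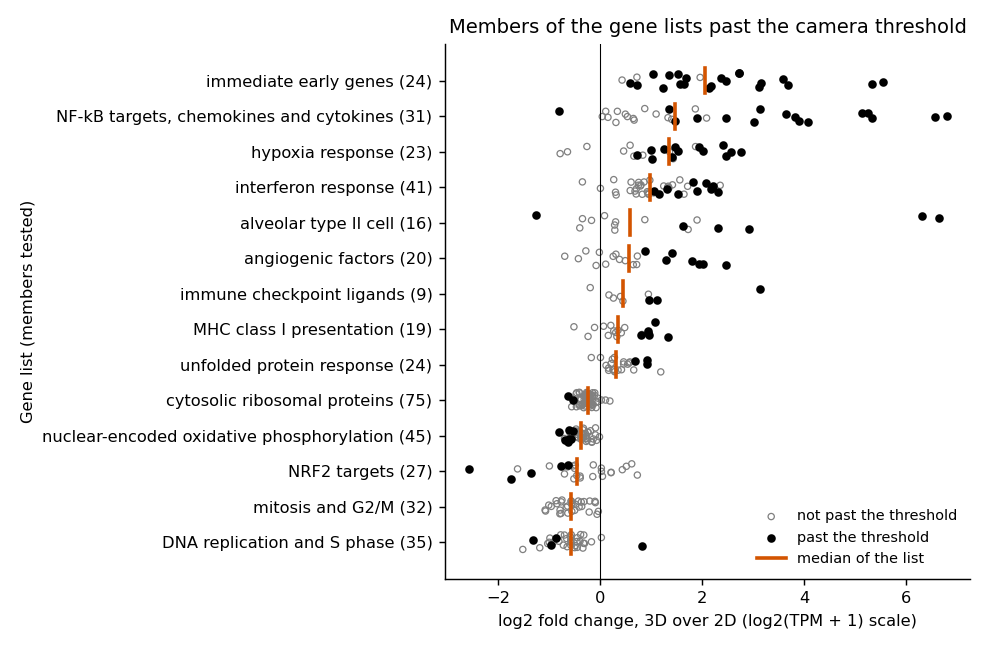
Log2 fold change of 3D over 2D for each measured member of the 14 gene lists called by camera with its preset correlation, with filled points for genes past the threshold and the list median as a bar. Immediate early genes had the highest median at 2.04 and DNA replication the lowest at -0.58; no list was called with an estimated correlation.

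The intermediate filament gene VIM, a mesenchymal marker, rose from 4.27 ± 3.08 to 39.4 ± 2.3 TPM (limma log2 fold change 3.11, SE 0.38, adjusted p = 0.00433). FN1, which encodes the matrix protein fibronectin, rose from 34.2 ± 6.17 to 168 ± 34.1 TPM and the collagen gene COL6A2 from 0.573 ± 0.280 to 6.71 ± 1.12 TPM. SNAI1, a transcription factor that represses epithelial genes, fell from 20.2 ± 4.09 to 8.68 ± 2.35 TPM, a call lost without 3D replicate 1 or 2D replicate 2 (limma, adjusted p up to 0.084 over the alternatives). Of 30 mesenchymal genes on the list 14 passed the filter on mean TPM. CDH2, at a mean of 0.01 TPM in 3D and 0 in 2D, and ZEB1, at 0.253 and 0.0867, were among those below it. Of the 14 tested genes 6 rose, 1 fell and 7 did not pass the test, the same numbers as when adjusted over the list alone. The list was not called in the main setting (camera, adjusted p = 0.083, median 0.59). It was called higher by fry (adjusted p = 0.0034), with no filter, under median-ratio scaling or quantile normalization, without 2D replicate 3 and after the length and GC correction. The epithelial markers CDH1, with 203 ± 27.2 TPM in 3D and 185 ± 33.5 in 2D, and EPCAM, with 576 ± 11.2 and 597 ± 30.5 TPM, did not pass the test. Of 24 matrix remodelling enzymes 9 rose, 2 fell and 13 did not pass the test, the same numbers as over the list alone (camera, adjusted p = 0.404, median 0.24; called with no filter and by fry). The collagenase MMP13 rose from 0.607 ± 0.229 to 12.8 ± 4.23 TPM and the gelatinase MMP9 from 0.203 ± 0.0764 to 7.95 ± 5.67 TPM.

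The receptors and other fixed genes of this cancer given here did not pass the test, apart from the calls on MYC, VIM, CD274 and VEGFA given above. EGFR had 457 ± 39.9 TPM in 3D and 381 ± 90.2 in 2D (limma log2 fold change 0.29, SE 0.18, adjusted p = 0.322), and was called higher only when both libraries numbered 3 were left out, an analysis chosen after seeing the data. MET had 188 ± 14.7 and 194 ± 20.5 TPM, ERBB2 71.7 ± 13.3 and 75.1 ± 13.6 TPM, and ERBB3 65.8 ± 5.29 and 58.5 ± 12.2 TPM. CCND1 had 89.5 ± 16.6 and 109 ± 13.9 TPM, and CD44 128.5 ± 4.85 and 181.5 ± 32.8 TPM. CD44, lower in 3D, passed the test under median-ratio scaling. AXL, a receptor linked to drug resistance, was below the filter at 0.643 TPM in 3D and 0.68 in 2D. Of 15 EGFR family members and ligands 2 rose, 1 fell and 12 did not pass the test, the same numbers as over the list alone (camera, adjusted p = 0.953). The ligand HBEGF rose from 1.07 ± 0.553 to 6.24 ± 2.51 TPM, a call lost without 3D replicate 1 or 2D replicate 2, and the ligand BTC fell from 17.6 ± 5.91 to 7.91 ± 1.90 TPM, a call lost without 3D replicate 1 or 2 or 2D replicate 1 or 2 (limma, adjusted p up to 0.0563 and 0.133 over the alternatives).

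MHC class II genes moved in opposite directions. HLA-DRB1 rose from 10.0 ± 1.92 to 35.7 ± 7.13 TPM (limma log2 fold change 1.73, SE 0.20, adjusted p = 0.00362) and HLA-DRB5 from 1.43 ± 0.543 to 21.2 ± 3.55 TPM (3.20, SE 0.21). These genes share reads, and their separate values are uncertain. CD74, the invariant chain that guides class II molecules, fell from 5.63 ± 1.20 to 2.01 ± 1.08 TPM (-1.18, SE 0.29), and its call was lost without 3D replicate 1, 3D replicate 3, 2D replicate 1 or 2D replicate 2 and after a correction for gene length and GC content (limma, adjusted p up to 0.122 over the alternatives). Of 7 measured class II genes 2 rose, 2 fell and 3 did not pass the test, with 3 rising and 4 falling when adjusted over the list alone. The median of the list was -0.87, its mean 0.14, camera placed it lower (higher under median-ratio scaling) and fry higher, and neither called it (camera, adjusted p = 0.713).

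On GRCh38, with 1-based coordinates of the GENCODE 29 gene models, CCL20 (ENSG00000115009) lies on the plus strand of chromosome 2 from 227805739 to 227817564. CXCL8 (ENSG00000169429) lies on chromosome 4 from 73740506 to 73743716 on the plus strand, and CXCL2 (ENSG00000081041) on the minus strand of the same chromosome from 74097035 to 74099293. SFTPA1 (ENSG00000122852) spans 79610939 to 79615455 on the plus strand of chromosome 10, and SFTPA2 (ENSG00000185303) spans 79555852 to 79560402 on its minus strand. IL6 (ENSG00000136244) lies on chromosome 7 from 22725884 to 22732002, ATF3 (ENSG00000162772) on chromosome 1 from 212565334 to 212620777 and FOSB (ENSG00000125740) on chromosome 19 from 45467995 to 45475179, each on the plus strand. VEGFA (ENSG00000112715) spans 43770184 to 43786487 on the plus strand of chromosome 6, and VIM (ENSG00000026025) spans 17228259 to 17237593 on that of chromosome 10. AKR1B10 (ENSG00000198074) spans 134527592 to 134541408 on the plus strand of chromosome 7 and GPX2 (ENSG00000176153) spans 64939152 to 64942905 on the minus strand of chromosome 14.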

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

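The settings that leave out both libraries numbered 3, correct for length and GC content, or keep protein-coding nuclear genes only were chosen after seeing the data. Of the 131 called genes named by rule, 60 kept their call in every setting run for them. Over 2594 refits of these genes 2224 kept the call, 370 lost it and 0 reversed; leaving out 1 library ended at least 1 call in 71 of them, having no filter ended 56, and median-ratio scaling or quantile normalization ended 14. The 19 uncalled genes gained a call in 9 of 372 refits and changed sign without a call in 18. The 14 called lists kept the call in 268 of 308 refits and lost it in 40. The 28 uncalled lists gained one in 60 of 612 and changed sign without a call in 56. The list of progenitor and drug tolerance genes, with a median of -0.065, was placed lower by camera without a call and called higher by fry; the cause was not tested. Counts that moved over 1.5-fold were as follows, in the order higher and lower in 3D. Against 1536 and 319 genes there were 729 and 86 with no filter, where more genes were tested, 931 and 662 with median-ratio scaling and 869 and 576 with quantile normalization, which move the median gene from 0.12 to -0.03 and -0.04. There were 2464 and 1356 without both libraries numbered 3; the cause was not tested. Without 1 library the counts ran from 367 to 1607 and from 29 to 563, with fewer samples in each fit. Against 717 and 111 genes changed at least 2-fold there were 298 and 49 with a pseudocount of 5, which shrinks folds, 428 and 29 with no filter, and 438 higher at a mean of 5 TPM, where fewer genes were tested. The lower count was 193 with median-ratio scaling, 202 with quantile normalization and 397 without both libraries numbered 3. Without 1 library these counts ran from 339 to 830 and from 24 to 225. Against 9 and 5 called lists there were 17 higher with no filter and 16 higher with quantile normalization, 0 and 0 with an estimated correlation, and 17 and 2 by fry, which tests another hypothesis; without 1 library they ran from 6 to 11 and from 5 to 6. Pairing by replicate number was not clear. Deviations from the group means correlated at 0.101, 0.036 and 0.185 for the numbers 1, 2 and 3, and 3D replicate 1 correlated best with 2D replicate 2, at 0.127. The value for number 3 was the highest across the groups, while 3D replicate 3 correlated at -0.112 and -0.140 with 2D replicates 1 and 2. A factor shared by the libraries numbered 3 is therefore not excluded. With the replicate block there were 1479 and 395 genes and 12 and 6 lists. TPM keeps no depth, so which calls were limited by depth cannot be assessed.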

Other observations

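Several gene groups outside the largest changes also held called genes, although none of the lists in these first 2 paragraphs passed the camera test in the main setting. Some were called under alternatives: ERK output in 10, the glycolysis and integrin lists in 8 each, basal cell genes in 6, the ATF4 list in 4, and cholesterol synthesis and TGF-beta targets in 3 each, while the ciliated cell, keratin, Wnt and progenitor lists were called only by fry. The cell cycle inhibitor CDKN1A rose from 6.78 ± 1.00 to 40.4 ± 5.49 TPM (limma log2 fold change 2.41, SE 0.16, n = 3 each). Of 23 TGF-beta targets 8 rose and 1 fell, over all genes and over the list alone (camera, adjusted p = 0.156), among them KLF10, from 51.1 ± 9.18 to 188 ± 7.67 TPM, and SMAD7, the feedback inhibitor of the pathway, from 5.95 ± 1.08 to 18.5 ± 1.77 TPM. Of 23 genes of ERK output 7 rose and none fell, 8 over the list alone (camera, adjusted p = 0.07). Of 10 Wnt targets 2 rose and none fell, 3 and 1 over the list alone (camera, adjusted p = 0.69); SOX9, a transcription factor of lung progenitors, rose from 0.23 ± 0.0346 to 11.6 ± 1.3 TPM. Of 14 Notch genes the ligand JAG1 rose and 2 fell, the same over the list alone (camera, adjusted p = 0.953). Of 24 genes of cholesterol synthesis 6 rose and none fell, the same over the list alone (camera, adjusted p = 0.15), among them SQLE, from 11.9 ± 1.43 to 30.1 ± 3.67 TPM. Of 15 genes of fatty acid synthesis FADS2 rose and SREBF1 fell, 1 and 3 over the list alone (camera, adjusted p = 0.118), and SREBF1 lost its call without 3D replicate 1 or 2 or 2D replicate 2. Of 18 glycolysis genes 3 rose and none fell, the same over the list alone (camera, adjusted p = 0.11); the glucose transporter SLC2A3 rose from 0.277 ± 0.323 to 13.5 ± 6.97 TPM. Of 29 ATF4 and amino acid genes ATF3 rose and 3 fell, the same over the list alone (camera, adjusted p = 0.058). Among those that fell was PHGDH, the first enzyme of serine synthesis, whose call was lost without 3D replicate 1. Of 17 heat shock genes 1 fell (HSPB1) and of 17 histone genes 1 fell, none in either over the list alone (camera, adjusted p = 0.897 and 0.974); HSPB1 lost its call in 15 of 20 alternatives, among them each fit without 1 library.

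Genes of airway and epithelial cell types moved in both directions. Of 15 ciliated cell genes 2 rose and none fell, 4 and 1 over the list alone (camera, adjusted p = 0.618): the tubulin TUBA1A, from 9.27 ± 2.15 to 130.7 ± 21.8 TPM, and TPPP3. Of 15 basal cell genes 4 rose and none fell, 7 over the list alone (camera, adjusted p = 0.0929), among them TP63, the defining transcription factor of basal cells, from 1.13 ± 0.0436 to 8.47 ± 3.25 TPM. Of 19 secretory cell genes 4 rose and 2 fell, 6 and 4 over the list alone (camera, adjusted p = 0.713). BPIFA1, an airway secretory protein, was listed at 0 in every 2D library and at 16.6, 102.8 and 7.53 TPM in the 3D libraries. Its call was lost with no filter and without 2D replicate 2 (limma, adjusted p up to 0.0563 over the alternatives). The alveolar type I list held 1 rise among 9 genes, EMP2, the same over the list alone (camera, adjusted p = 0.897). Of 13 liver and intestinal genes 4 rose and none fell, 5 and 1 over the list alone (camera, adjusted p = 0.15). Of 21 desmosome and keratin genes 7 rose and 1 fell, 7 and 2 over the list alone (camera, adjusted p = 0.753); DSP, the desmosomal plaque protein, rose from 15.5 ± 3.65 to 51.9 ± 3.89 TPM. Of 32 adhesion genes 3 rose and 1 fell, 5 and 2 over the list alone (camera, adjusted p = 0.923). Of 20 basement membrane genes 4 rose and 2 fell, 4 and 3 over the list alone (camera, adjusted p = 0.711), of 31 integrin and focal adhesion genes 4 rose and 2 fell, the same over the list alone (camera, adjusted p = 0.0545), and of 25 actin genes 2 rose and none fell, the same over the list alone (camera, adjusted p = 0.618). Of 23 YAP/TAZ targets 2 rose and 2 fell, 4 and 3 over the list alone (camera, adjusted p = 0.406). Of 14 progenitor genes 4 rose, KLF4 and BMI1 among them, and 3 fell, 4 and 4 over the list alone (camera, adjusted p = 0.618). Median, mean and test differed in sign for the keratin list (median -0.05, mean 0.30, placed higher), the integrin list (-0.14, 0.01, lower), the ATF4 list (-0.13, 0.09, lower) and the progenitor list (-0.07, 0.06, lower). The adhesion, basement membrane, YAP/TAZ, actin, EGFR family, heat shock and Notch lists had positive medians and means and were placed lower by camera. Camera compares a list with the other genes, and the median of all tested genes was 0.12. The first 5 of these lists had medians below that, at 0.10, 0.04, 0.09, 0.03 and 0.07. For the heat shock and Notch lists, with medians of 0.19 and 0.27, the cause was not tested. Lists of other cell types and the neuroendocrine list had fewer than 5 tested members and no list test; among those tested 2 of 3 fibroblast and 1 of 4 neuroendocrine genes rose (2 and 2 over each list alone), and 0 of 3 leukocyte and 0 of 1 endothelial genes passed the test. Median levels over all their genes in 3D were 0.0733 TPM for fibroblast, 0.0383 for endothelial, 0.177 for leukocyte and 0.0567 for neuroendocrine genes. COL1A1 rose from 2.3 to 7.56 TPM on average while COL1A2 and COL3A1 stayed at or near 0 in all libraries; its call was lost with no filter and without 3D replicate 2 or 2D replicate 1 or 2. CD68 had 69.4 ± 21.7 TPM in 3D and 86.6 ± 15.7 in 2D without passing the test.

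For the patterns below, the tests of leukocyte RNA, scaling, handling, the TPM scale and both tests of class II genes were chosen after the results were seen, as was the use of the range without any 1 library as the spread of a share of higher calls. The bounds for those shares, under 60% or over 75%, were set before, and that range crosses the upper bound. A rule tried in between, which asked that the share stay over 75% without any 1 library, left both share tests undecided. No other division of the 6 libraries into 3 and 3 gave as many called genes: the cultures gave 1855 and the highest other division 1, and 828 against 1 for genes changed at least 2-fold, so 1 of 10 divisions reached each count. For called lists 3 of the 10 divisions gave at least the 14 of the cultures, the highest other giving 17. With 10 divisions the share cannot fall under 0.1, so these counts are too few for a share under 0.05. Each other division also set 2 libraries from 1 culture with 1 from the other, and so kept part of the culture difference.

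The rise of immediate early and NF-kB target genes in 3D was weighed against 3 explanations. RNA of leukocytes would bring their abundant transcripts, and the highest level of PTPRC, TYROBP, LAPTM5 and FCER1G in any 3D library was 1.03 TPM, which argues against it. Scaling between libraries was not decided by rescaling, since median ratios give each library a single factor that moves all genes nearly alike. Under that scaling the median of the members of both lists lay 1.72 above that of all genes, a distance that such a factor hardly changes. It shows only that the members rose more than the typical gene. A response to handling at harvest may contribute and stays open, because the labels do not describe how the cells of either culture were taken for RNA. The heat shock list had a median of 0.19 against 0.12 for all genes, but handling can induce immediate early genes without heat shock genes. Effects of culture geometry, of the longer culture time, of the gel or of the number of cells seeded are equally untested.

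The excess of higher over lower calls in 3D, 82.8% of called genes, may come in part from the TPM scale. After correcting for gene length and GC content the share was 83.6%, and between 73.5% and 92.5% without any 1 library. The correction kept the mean of each library, so it could not remove a shift common to all genes and does not decide this explanation. The excess remained once trends around that mean were taken out. A few abundant genes were argued against as the whole cause, with 78.9% after the 50 most abundant were left out and 70.2% to 90.4% without any 1 library. Under median-ratio scaling the share was 58.4%, but centring the median gene fixes that outcome, so whether the total RNA composition or many small increases lie behind the excess cannot be told apart. The share was also 64.5% without both libraries numbered 3.

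HLA-DRB1 and HLA-DRB5 rose in 3D while CD74 and HLA-DRA fell. Reads shared between the pair were argued against as the whole cause, since their summed level was 56.8 ± 10.4 TPM in 3D and 11.4 ± 2.41 in 2D, a log2 ratio of 2.31 with every 3D library above every 2D library. RNA of antigen-presenting cells would raise CD74 and HLA-DRA, but CD74 had a log2 fold change of -1.18 (limma SE 0.29), although its call was lost with no filter, after the length and GC correction and without 3D replicate 1 or 3 or 2D replicate 1 or 2, and HLA-DRA had 1.36 ± 0.344 TPM in 3D and 4.31 ± 1.68 in 2D. Reads placed by the alleles of this line against the reference, and regulation by the culture, stay open and untested, so a separate control of the DRB genes is a hypothesis that may be followed up.

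The keratin gene KRT16 rose from 0.463 ± 0.130 to 3.60 ± 1.26 TPM while its pseudogenes KRT16P1, KRT16P2 and KRT16P3 fell from 403 ± 44.6, 101.4 ± 13.9 and 85.6 ± 19.5 TPM to 124 ± 26.0, 34.5 ± 5.91 and 27.1 ± 6.14 TPM, and reads can be shared among these copies. Among the libraries of each group replicate 3 had the highest levels of GAPDH (8288 TPM in 3D and 9845 in 2D, against 4132 to 5227 in the other libraries) and of PGK1 (6085 and 5957 TPM, against 1280 to 3275).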
